A study of Homo sapiens with 10 samples.

How the data were processed

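The H3K27ac HiChIP libraries were, per the submitters' processing notes, aligned to hg19 (GRCh37) with Bowtie2 and HiC-Pro, without versions. The loop caller, its significance threshold, the merging of libraries, the way nodes were grouped into cliques and the way gene names were assigned to cliques are not given in the sources used here. The proliferating cells were at population doublings 28 and 30 and the OIS cells at 27 and 34, so the conditions were not matched in population doubling. The authors' tables give, for each pooled network, every clique with its number of nodes, its node names and its gene names, and the hg19 position of every node. They give no edges, loop strengths, peak calls or values per library. Connectivity is therefore the number of nodes of a clique, the choice set in the design for tables without edges.

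Every node was a 5 kb bin, and the number of nodes counted from the node names equalled the number given for the clique in both networks. A name listed in more than 1 clique of a network, or in cliques on different chromosomes in the 2 networks, was left out (56 names, 3 of them on different chromosomes), which left 23731 gene names. Of these 11954 (50.4%) matched a protein-coding symbol. No hg19 gene annotation was at hand, so the position of a gene within its clique is not given and a gene's stretch is the span of the cliques that list it; the 1 Mb window is centred on the part these cliques share. Depth could not be equalised; clique sizes were scaled to the mean of the 2 node totals, and a pseudocount of 1 was added before the log2 ratio.

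Hyperconnected cliques were those above the point where the curve of ranked sizes, with both axes scaled to run from 0 to 1, has slope 1. Shared nodes are identical bins. The background for sharing came from 100 circular shifts of the proliferating nodes along each chromosome up to its last node, each by at least 1000 kb. Grouping of shared nodes was compared by the adjusted Rand index and by pairs in 1 clique, and whole cliques by the Jaccard index of their nodes. Percentages carry exact (Clopper-Pearson) 95% binomial intervals. The interval of a chromosome came from 1000 bootstrap draws of 5 Mb blocks. The interval of the coefficient within chromosomes came from 1000 redraws of the chromosomes.

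The 19 gene lists held 446 entries, of which 357 were in either network, 3 of them under an older symbol. For each list 10000 random lists of equal size were drawn from 10 strata of mean clique size over the 2 networks, and the percentile of the list median among their medians is given. In simulated data, 100 lists of 20 genes without a planted shift lay in the upper 2.5% of the random medians in 2% of cases. Lists with a planted log2 shift of 1 and 2 did so in 63% and 93%. For lists of 30 genes the shares were 2%, 87% and 100%. Simulated genes were drawn singly from all names, so these shares do not cover lists whose genes share cliques, such as the cytokine and HOX lists.

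The genes named first are the 12 with the largest scaled difference in nodes in each direction, at most 1 per clique. Within a clique whose genes tie, the first name by alphabet was taken among those matched to a protein-coding symbol; the narrowing to such symbols was added after the files were seen. From each list, members with the largest differences were named, and further members were chosen after their values were seen. Genes named in the largest cliques were likewise chosen after the cliques were seen. Some genes that these rules select are not reported.

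Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.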

Results

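H3K27ac HiChIP couples chromatin immunoprecipitation for a histone mark of active promoters and enhancers to proximity ligation, and so reads out contacts between marked loci. It was run on IMR90 cells, a line of human lung fibroblasts. The cells were either proliferating or had entered oncogene-induced senescence (OIS), a lasting arrest that follows retroviral expression of HRasV12, an activated RAS protein. Each condition had 5 libraries from 2 biological replicates, with replicate 1 made in 2 technical batches and replicate 2 in 3. The authors' tables give 1 network per condition: 5 kb bins of hg19 (nodes), sorted into groups of linked nodes (cliques), each with the names of the genes it was assigned. Both networks pool their libraries, so no spread between replicates, no test and no p-value can be given, and the sequencing depth behind each network is unknown. Every difference below is a difference between these 2 pooled networks.

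The first comparison asked how the enhancer network as a whole differed between the conditions. The clique with the most nodes in OIS held 367 nodes on chromosome 2 (26170001 to 32055000) and listed FOSL2, an AP-1 transcription factor, with 70 further gene names. In proliferating cells FOSL2 was listed in a clique of 263 nodes at 26575001 to 29135000. OIS cliques of 338 nodes on chromosome 3 (185370001 to 188955000; ETV5, BCL6 and LPP), 335 nodes on chromosome 10 (1155001 to 5920000; KLF6, PFKP and NET1), 298 nodes on chromosome 10 (78910001 to 81980000; ZMIZ1, KCNMA1 and ANXA11) and 293 nodes on chromosome 9 (117110001 to 119755000; TNC, PAPPA and TRIM32) came next. In proliferating cells the clique with the most nodes held 274 on chromosome 1 (27225001 to 31410000; SESN2, IFI6 and RCC1). It was followed by cliques of 270 nodes on chromosome 11 (10790001 to 13690000; TEAD1, EIF4G2 and PARVA), 265 nodes on chromosome 2 (45835001 to 48030000; EPAS1, SOCS5 and CALM2), the FOSL2 clique, and 262 nodes on chromosome 7 (97875001 to 100945000; MCM7, TRRAP and EPHB4).

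The OIS network was smaller in total, with 92559 nodes against 98312 (−5.85%), 3803 cliques against 3975 (−4.33%; 2594 against 2577 among cliques of at least 3 nodes) and 18694 gene names against 20636 (−9.41%). No clique in either network spanned more than 1 chromosome. The median clique held 5 nodes in both conditions, while the 99th percentile was 214 nodes in OIS and 194 in proliferating cells. Cliques of over 200 nodes numbered 52 in OIS, with 12905 nodes, and 32 in proliferating cells, with 7474 nodes. Cliques of 2 nodes made up 31.8% of the OIS cliques (exact 95% binomial interval 30.3 to 33.3%) and 35.2% of the proliferating cliques (33.7 to 36.7%). Cliques that listed no gene (named nonpromoter by the authors) made up 31.4% (29.9 to 32.9%) and 31.5% (30.1 to 33.0%), with a median of 2 nodes in each. These intervals cover counting error only, and neighbouring nodes and cliques are not independent.

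**Figure D1:**
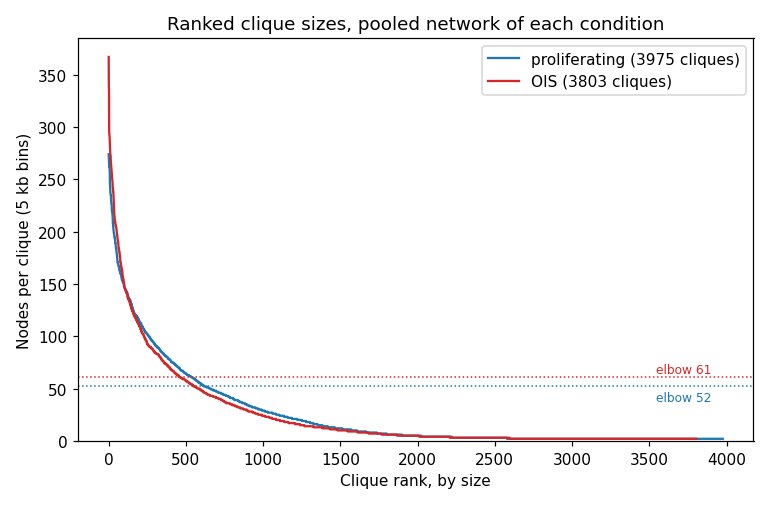
Nodes per clique (5 kb bins, vertical axis) against the rank of the clique by size (horizontal axis) in the pooled network of each condition, with dotted lines at the elbow of each curve. The OIS curve starts higher, at 367 nodes against 274, and lies below the proliferating curve over the middle ranks, with elbows at 61 and 52 nodes.

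Cliques above the elbow of the ranked curve were called hyperconnected. By this rule 455 OIS cliques (over 61 nodes) and 616 proliferating cliques (over 52 nodes) were hyperconnected, with 9319 and 12458 gene names. They held 59.2% of the OIS nodes (58.9 to 59.5%) and 65.6% of the proliferating nodes (65.3 to 65.9%), and their median span was 1730 kb in OIS and 1255 kb in proliferating cells. Among the listed genes described below, MMP1, BMP2, EREG and RUNX1 stood in a hyperconnected clique in OIS only, and CDC6, E2F1 and POLR2A in proliferating cells only. The order of the hyperconnected counts depended on the measure: ranked by genomic span in place of nodes, 592 OIS and 501 proliferating cliques lay above the elbow.

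The next comparison asked how far the networks used the same sites. Of the proliferating nodes, 62207 (63.3%, 63.0 to 63.6%) were also OIS nodes, and these were 67.2% (66.9 to 67.5%) of the OIS nodes. Shifting the proliferating nodes along their chromosomes placed on average 15.8% of them on OIS nodes (14.5 to 16.8% over 100 shifts). Gene names were shared more often: 15543 names stood in both networks, 75.3% of the proliferating names and 83.1% of the OIS names. VCAM1, an adhesion receptor, and ELN, which encodes elastin, were among the 5093 names of the proliferating network only, and IL1A, IL1B and MMP3 among the 3151 of the OIS network only. Shared nodes were mostly grouped alike, with an adjusted Rand index of 0.782 between their cliques. Pairs of shared nodes in 1 proliferating clique were together in OIS in 83.2% of cases, and pairs in 1 OIS clique were together in proliferating cells in 73.7%. Each clique lies on 1 chromosome, and no background for grouping by position alone was made. The index and the pair shares therefore do not separate kept grouping from nearness along the chromosome. No hyperconnected clique of either network lacked a shared node, whereas 729 proliferating cliques (18.3%) and 809 OIS cliques (21.3%) had none, with a median of 2 nodes. A larger clique has more nodes that can be shared, so this contrast largely restates clique size. Whole cliques overlapped only in part: the best matching OIS clique of a hyperconnected proliferating clique had a median Jaccard index of 0.435, and the reverse median was 0.441.

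The central comparison here was between the cliques that list each gene in the 2 states. Each gene was given the number of nodes of the clique that lists it, or 0 where none does, and the change is the log2 ratio of these numbers after scaling to equal network totals with a pseudocount of 1. Among the 12 genes with the largest difference toward OIS, at most 1 per clique, were RAB10 (367 nodes in OIS), a GTPase of vesicle traffic, CRYGS (338), CALML5 (335), SFTPA2 (298), which encodes a surfactant protein, C14orf105 (292), AMPD1 (290), ACTL7A (280), LIX1 (280), KCNAB1 (275), PSMA2 (269), a proteasome subunit, and CBR1 (267). None of these 12 was listed in a proliferating clique. The 12 with the largest difference toward proliferating cells were CD164L2 (274 nodes in proliferating cells), EIF4G2 (270), a translation factor, ATP6V1E2 (265), DPYSL5 (263), AGFG2 (262), MTSS1 (262), FBXO31 (260), CDC6 (246), which loads the replicative helicase, DAG1 (244), ARHGAP20 (241), C11orf16 (237) and C9orf78 (236). None of these 12 was listed in an OIS clique. Within a clique the difference is largest for a gene unlisted in the other network, so the rule favours such genes. Both networks covered the chromatin of these genes: the stretches of the 12 OIS cliques held 165 to 419 proliferating nodes, and those of the 12 proliferating cliques held 155 to 293 OIS nodes. Over the stretch the direction turned after scaling for RAB10 (419 proliferating and 377 OIS nodes), C14orf105 (328 and 296) and CD164L2 (280 and 293).

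Over 23731 gene names, 5869 (24.7%) were at least 2-fold higher in OIS and 8251 (34.8%) at least 2-fold lower, with a median log2 change of −0.29. Names listed in 1 network only supplied 3151 of the 5869 and 5092 of the 8251, and 248 and 338 of them lay in stretches without a node of the other network. Counting nodes of both networks over the same stretch, the span of the cliques that list the gene, gave 1007 names at least 2-fold higher and 937 at least 2-fold lower. In a 1 Mb window centred on the gene's cliques, 1020 names were at least 2-fold higher and 354 lower, so that 74.2% of such names were higher, against 41.6% by clique size. This share covers only the few names that changed at least 2-fold. Most names changed less, and random lists leaned lower in OIS in the window. Those matched to the cell cycle and housekeeping lists described below had medians of −0.18 and −0.20.

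Genes of the secretory programme of senescent cells (SASP) were examined as lists fixed before the data were examined. Of 29 cytokine, chemokine and growth factor genes, 18 were listed in proliferating cliques and 23 in OIS cliques, and 14 and 20 of them stood in hyperconnected cliques. Over the 23 listed genes, with 0 for a gene in no clique, the median number of nodes was 59 in proliferating cells and 146 in OIS. Of these genes 18 were higher in OIS, 13 of them at least 2-fold. The chemokine genes CXCL1, CXCL2 and CXCL3 stood in a clique of 59 nodes in proliferating cells and 184 nodes in OIS, in the stretch from 73930001 to 76500000 of chromosome 4. The OIS clique also listed CXCL8 and CXCL5, which were in no proliferating clique, and EREG, an EGF receptor ligand with 45 nodes in proliferating cells. This stretch held 107 proliferating and 184 OIS nodes. INHBA, which encodes the activin A subunit, stood in cliques of 81 and 269 nodes on chromosome 7 (40140001 to 43970000, 165 and 271 nodes over the stretch), and BMP2 in cliques of 19 and 176 nodes on chromosome 20 (6090001 to 8725000, 53 and 188 nodes).

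IL1A and IL1B, upstream inducers of the secretory programme, were in no proliferating clique and in an OIS clique of 73 nodes on chromosome 2, but their stretch (112640001 to 113725000) held 74 proliferating and 73 OIS nodes. IL6 stood in cliques of 75 and 114 nodes, CSF2 of 77 and 146, STC1 of 107 and 205 and VEGFA of 100 and 131 in proliferating and OIS cells. Over their stretches the numbers were 106 and 114 for IL6, 115 and 155 for CSF2, 196 and 205 for STC1 and 142 and 131 for VEGFA. The 5 genes listed lower in OIS were GDF15 (40 and 7 nodes), IL32 (37 and 17), CCL2 (86 and 69), CSF3 (246 and 190) and IL11 (147 and 113). CXCL6, CCL7, CCL8, CCL26, AREG and IL33 were not listed in either table used here. The list median log2 change was 1.02 (95% order-statistic interval over genes 0.19 to 2.09), at percentile 99.9 of 10000 random lists of equal size matched on clique size, of whose medians the central 95% lay between −0.67 and 0.48. Counted over the same stretch in both networks, the list median was 0.15 (−0.06 to 0.86), at percentile 99.6, and with 1 gene per OIS clique it was 0.68 (−0.23 to 1.71), so these intervals include 0. The percentile describes these networks and is not a test, and genes that share a clique are not independent.

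**Figure D2:**
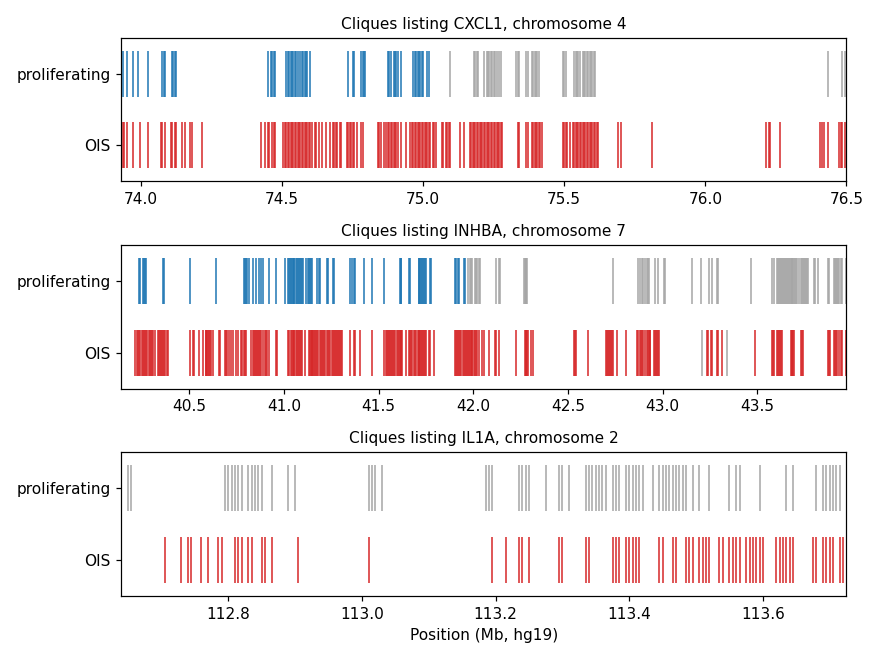
Nodes (5 kb bins, vertical ticks) of the proliferating and OIS networks along 3 stretches of hg19 (position in Mb), coloured where they belong to the clique that lists CXCL1, INHBA or IL1A and grey where they belong to other cliques. The CXCL1 stretch holds 107 and 184 nodes, the INHBA stretch 165 and 271, and the IL1A stretch 74 and 73, where no proliferating clique lists IL1A.

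Of 22 secreted protease, protease inhibitor and IGF binding protein genes, 16 were listed in proliferating cliques and 19 in OIS cliques, and 13 of the 20 listed in either were higher in OIS. MMP3, MMP10 and MMP12 were in no proliferating clique and MMP1 in one of 2 nodes, while all 4 matrix metalloproteinase genes stood in an OIS clique of 119 nodes on chromosome 11. The stretch held 103 proliferating and 135 OIS nodes. IGFBP7, which binds insulin-like growth factors, stood in cliques of 80 and 243 nodes (239 and 252 over the stretch) and TIMP1, a metalloproteinase inhibitor, of 35 and 86 (91 and 86). IGFBP2 stood in a clique of 204 nodes in proliferating cells and in none in OIS. The list median was 0.40 (−0.16 to 1.68), at percentile 92.0, but below 0 over the same stretch (−0.005) and in the 1 Mb window (−0.06). Matched random medians were lower in these counts (−0.14 and −0.19), so the list lay at percentiles 92.5 and 86.3.

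**Figure D3:**
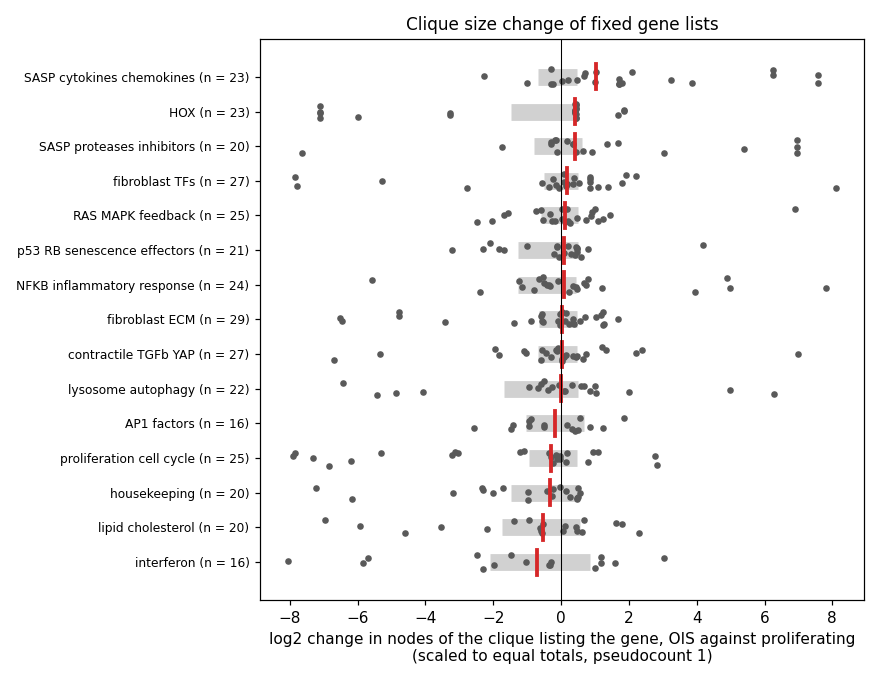
Log2 change of the nodes of the clique that lists each gene, OIS against proliferating, scaled to equal totals with a pseudocount of 1 (horizontal axis), for the members of 15 lists fixed before the data were examined. Points are genes, red bars are list medians, and grey boxes hold the central 95% of the medians of 10000 matched random lists; the bar of the cytokine list lies at 1.02, right of its box, and that of the HOX list at 0.41.

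Of 35 cell cycle genes, 25 were listed in proliferating cliques and 19 of these in OIS cliques. Of all proliferating names, 75.3% were listed in OIS. Hyperconnected cliques listed 17 of the genes in proliferating cells and 10 in OIS. Over the 25 genes, with 0 for a gene in no clique, the median number of nodes was 114 in proliferating cells and 46 in OIS. CDC6 (246 nodes), BUB1B (235), MCM5 (163), CDC20 (118), E2F1 (75) and BUB1 (8) were listed in proliferating cells only, while their stretches held 210, 236, 131, 71, 45 and 1 OIS nodes. These genes act in replication licensing, the spindle checkpoint and entry into S phase. FOXM1, a transcription factor of mitotic genes, stood in cliques of 208 and 4 nodes (210 and 140 over the stretch), CDC25A of 244 and 24 (248 and 155), and CCNB1 of 42 and 4 (42 and 24). The 3 genes at least 2-fold higher in OIS were E2F7 (16 and 109 nodes; 24 and 109 over the stretch), TYMS (6 and 46; 37 and 46) and AURKA (27 and 55; 38 and 60). MKI67, CDK1 and PLK1 were not listed in either table used here. In all, 18 of the 25 were lower in OIS, with a list median of −0.28 (−3.13 to −0.02). That was percentile 43.0 of matched random lists, so the list did not stand apart from other genes of like clique size.

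Senescence effectors of the p53 and RB pathways showed values in both directions, with 11 of 21 listed genes higher in OIS and 10 lower. CDKN2A and CDKN2B, which encode the inhibitors p16 and p15 of cyclin-dependent kinases, stood in 1 clique of 79 nodes in proliferating cells and 103 in OIS. MDM2, the p53 ubiquitin ligase, stood in cliques of 3 and 68 nodes (83 and 71 over the stretch), HMGA1 of 172 and 225 (322 and 239), and CDKN1A, which encodes p21, of 29 and 34 (47 and 43). LMNB1, the lamin B1 gene, stood in cliques of 48 and 4 nodes, SESN2 of 274 and 60 (280 and 293 over the stretch), BTG2 of 160 and 46 and CDKN1B of 171 and 79. The list median was 0.08, at percentile 84.2.

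Genes of RAS and MAPK feedback were higher in OIS for 15 of 25. ETV5, a transcription factor downstream of ERK, stood in cliques of 2 and 338 nodes (282 and 338 over the stretch), DUSP6, an ERK phosphatase, of 93 and 241 (112 and 243), DUSP10 of 126 and 255 (201 and 257) and SPRY2 of 61 and 136 (72 and 136). ELK3 stood in cliques of 135 and 30 nodes and EGR1 of 189 and 119. HRAS itself stood in cliques of 93 and 15 nodes; this is the gene's own locus and does not measure the retroviral copy. The list median was 0.13, at percentile 74.0. Among 16 AP-1 and related factors 8 were higher and 8 lower, with a median of −0.16 at percentile 52.5: FOSL2 stood in cliques of 263 and 367 nodes and MAFF of 91 and 202, but FOSL1 of 183 and 28 and MAFK of 176 and 61.

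Of 24 listed genes of the NF-κB response, 12 were higher and 12 lower, with a median of 0.08 at percentile 86.5. TNFAIP6 (0 and 217 nodes), BIRC3 (3 and 119) and RELA (0 and 28) were higher in OIS, and NFKB2 (178 and 31), PTGES (236 and 99) and VCAM1 (48 and 0) lower. The OIS clique of BIRC3 was the clique of MMP1 on chromosome 11. In the same way CSF3, CDC6 and ACLY, from different lists, shared 1 proliferating clique of 246 nodes. Changes in different lists can thus be the change of 1 clique. Interferon genes were lower for 11 of 16, with a median of −0.70 at percentile 26.8. IFI6 (274 and 0), IRF7 (93 and 15) and IFIT1 (58 and 0) were lower, whereas IRF1 (77 and 146), IFIT2 (58 and 124) and IFI44L (4 and 38) were higher.

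Extracellular matrix genes divided evenly, 15 of 29 higher and 14 lower. TNC, which encodes tenascin C, stood in cliques of 128 and 293 nodes (250 and 295 over the stretch), LOXL2 of 107 and 205 (196 and 205), COL4A1 and COL4A2 of 64 and 144 (160 and 152) and POSTN of 30 and 92 (63 and 92). COL1A1 stood in cliques of 146 and 52 nodes (167 and 110), and LOXL1 (94 nodes; 99 and 89) and ELN (90; 90 and 63) were listed in proliferating cells only. Among 27 contractile, TGF-β and YAP target genes, 14 were higher and 13 lower. CCN2, a YAP target, stood in cliques of 60 and 265 nodes, SKIL of 0 and 121 and SRF of 26 and 131, although their stretches held 291 and 267, 140 and 125, and 143 and 131 nodes, against CALD1 of 105 and 0 and ACTA2, the smooth muscle actin gene of myofibroblasts, of 48 and 12. The medians of these lists were 0.04 and 0.02, at percentiles 75.4 and 74.6.

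Transcription factors of fibroblast identity were higher in OIS for 18 of 27, with a median of 0.18 at percentile 78.9; over the same stretch the median was 0.10 at percentile 99.2, and in the 1 Mb window 0.01 at percentile 95.2. RUNX1 was in no proliferating clique and in an OIS clique of 267 nodes on chromosome 21 (35285001 to 37495000), where proliferating cells had 167 nodes. KLF4 stood in cliques of 64 and 280 nodes (247 and 282 over the stretch), KLF6 of 195 and 335 (270 and 335), TBX3 and TBX5 of 160 and 274 (164 and 274), and ZEB2 of 37 and 123 (43 and 125). NFIX (227 nodes) and PRRX2 (236) were listed in proliferating cells only. Of 23 listed HOX genes 16 were higher and 7 lower, in only 5 proliferating and 3 OIS cliques. HOXB2 to HOXB5, HOXB8 and HOXB9 stood in a clique of 82 and 103 nodes and HOXA2 to HOXA7 of 64 and 83, while HOXC4, HOXC5, HOXC6 and HOXC8 stood in a proliferating clique of 142 nodes and in no OIS clique. The HOX median was 0.41, at percentile 97.8, and −4.63 with 1 gene per OIS clique, which keeps each unlisted gene.

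Lysosome and autophagy genes divided 11 to 11, with CTSS (2 and 89 nodes), ATG7 (0 and 74) and TFE3 (22 and 86) higher and SQSTM1 (142 and 7), CTSZ (87 and 0) and MITF (43 and 0) lower. Lipid and cholesterol genes were lower for 11 of 20, among them ACLY (246 and 19), which makes cytosolic acetyl-CoA, and FASN (128 and 0), the fatty acid synthase, while INSIG1 (23 and 77) and ABCG1 (8 and 41) were higher. Housekeeping genes were lower for 13 of 20, 7 of them at least 2-fold and none at least 2-fold higher, with POLR2A (154 and 0), GAPDH (189 and 90) and B2M (104 and 10) at the low end and RPS18 (169 and 225) at the high end. The medians of these lists were 0.01, −0.54 and −0.34, at percentiles 82.8, 32.2 and 45.2. Over the same stretch the housekeeping median was −0.36, at percentile 2.91, and in the 1 Mb window −0.27, at percentile 26.3. Markers of other cell types were mostly not listed: 7 of 16 epithelial, 5 of 12 endothelial, 4 of 14 immune and 3 of 12 neural genes stood in either network, with medians of −0.28, −0.05, −2.04 and −1.56.

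Several list medians depended on how nodes were counted and the list was summarised. Over the same stretch the NF-κB (−0.14), contractile (−0.09), lysosome (−0.15) and, barely, p53 and RB (−0.0005) medians also lay below 0. Their matched random lists had medians of −0.14 to −0.18, so the sign does not set these lists apart. Their percentiles were 63.7, 70.9, 60.75 and 92.5, against 86.5, 74.6, 82.8 and 84.2 by clique size. In the 1 Mb window the RAS and MAPK (−0.07) and matrix (−0.02) medians lay below 0. Their percentiles there were 81.0 and 94.75, with random medians of −0.16 and −0.17. Of 72 list members at least 2-fold higher by clique size, 52 were higher over their stretch, 9 of them at least 2-fold, and 20 were lower. Of 85 at least 2-fold lower, 73 were lower over their stretch, 9 of them at least 2-fold, and 12 were higher. Besides VEGFA, BUB1B, MDM2, HMGA1, CDKN1A, SESN2, CCN2, SKIL and SRF above, the named list members with a turned direction after scaling were MAFF (232 and 205 nodes over the stretch), FOSL2 (419 and 377), RELA (34 and 28), IL32 (37 and 37), IFI6 (280 and 293), IFIT2 (135 and 124), ATG7 (112 and 78), CTSS (105 and 89), TFE3 (93 and 86), CTSZ (87 and 97), POLR2A (165 and 161) and RPS18 (341 and 245). The means had the opposite sign of the medians for the p53 and RB (−0.20), matrix (−0.69), contractile (−0.12), fibroblast factor (−0.12), HOX (−1.30), lysosome (−0.28) and endothelial (0.88) lists. Without scaling, the NF-κB, matrix, contractile and lysosome medians, all within 0.08 of 0, lay below 0, and the p53 and RB median was 0.

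Nodes were also compared by chromosome. Gene-rich chromosome 19 held 3004 proliferating and 2160 OIS nodes (−28.1%), chromosome 22 held 2116 and 1530 (−27.7%) and chromosome 17 held 4747 and 3768 (−20.6%). Gene-poor chromosome 4 held 4141 and 4490 (8.43% more) and chromosome 13 held 2412 and 2629, whereas gene-poor chromosomes X and 18 had fewer OIS nodes (−2.00% and −2.56%). After scaling to equal totals, the 95% interval of the log2 node ratio from a bootstrap of 5 Mb blocks lay above 0 for chromosomes 4, 5, 6, 8 and 13 and below 0 for 15, 16, 17, 19 and 22. Without scaling, which adds 0.09, 7 of the 23 chromosomes, 4 and 13 among them, had more OIS nodes, but no interval lay above 0 and 10 lay below 0. Across the 23 chromosomes the Spearman coefficient between gene names per Mb and the node ratio was −0.806. The intervals reflect the spread along each chromosome of the pooled networks, not that between replicates.

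**Figure D4:**
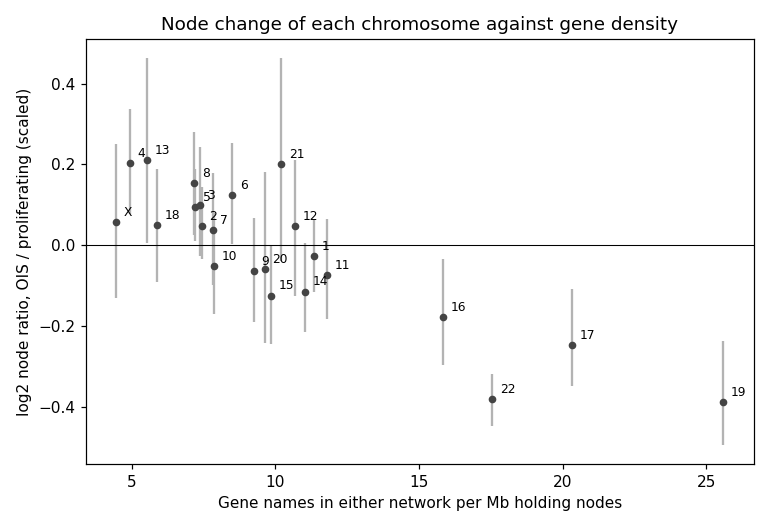
Log2 ratio of OIS to proliferating nodes of each chromosome, scaled to equal totals (vertical axis), against the gene names listed in either network per Mb that holds nodes (horizontal axis). Points are the 23 chromosomes and bars the 95% bootstrap intervals over 5 Mb blocks; chromosome 19 lies lowest at −0.39 with 25.6 names per Mb, and chromosomes 13 and 4 lie at 0.21 and 0.20 with 5.54 and 4.95.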

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

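Of 304 values under alternative settings, 273 stayed within the tolerance (the 95% interval of a list median or percentage, 1.5 times a count), 27 moved beyond it and 4 reversed for a list outside its random range; unless the construction shows it, the cause was not tested. Of 245 list medians, 37 (in 11 lists) had the other sign, 33 of them within the list's wide interval. A list median cannot move where only the random lists change (unmatched, protein-coding or matched on gene density). The counts of values that stayed and of signs that held therefore overstate how far the results held. With cliques of at least 3 nodes, 2577 proliferating and 2594 OIS cliques remained, so the order of the counts turned, and the medians were 18 and 14 nodes in proliferating cells and OIS; with at least 5 nodes, 2023 and 2009 cliques remained with medians of 28 and 24, since small cliques are left out by construction. Taking the top 5% of cliques gave 198 and 190 hyperconnected cliques. Counting nodes within 5 kb as shared, 81.2% of proliferating and 79.1% of OIS nodes were shared; between hyperconnected cliques only, 49.6% and 58.5%. Without scaling, 39.6% of 2-fold genes were higher in OIS. Among genes listed in both conditions 2718 were at least 2-fold higher and 3159 lower (46.2% higher). The settings from here on were added after the data were seen. With protein-coding names only, the counts were 2601 and 4110 (38.8%). With nodes counted over the same stretch in both networks they were 1007 and 937 (51.8%), and the SASP cytokine median was 0.15. In a 1 Mb window they were 1020 and 354 of 23731 names (74.2% of these 2-fold names were higher), and the SASP cytokine median was 0.34. The HOX median reversed to −4.63 with 1 gene per OIS clique (by either matching), to −4.63 with the median of each OIS clique, and to −0.33 with 1 gene per OIS clique in the 1 Mb window; in these settings HOX genes in no OIS clique stay single while the listed ones collapse into 3 cliques. No paired analysis was possible because each condition has 1 pooled network and no table carries a replicate number. Alternatives that need edges (a node's own degree, equal numbers of edges) or distances to promoters were not run, as the tables give neither. A 50% reciprocal overlap of nodes equals identity, as all nodes are bins of 1 grid.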

Other observations

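Single regions of 1 Mb showed where OIS cells had more nodes; these were chosen after the data were seen, as those with the largest scaled differences, and are named by genes of the clique that holds most of their nodes. On chromosome 8 (128000001 to 129000000) nodes numbered 78 in proliferating cells and 154 in OIS, and the cliques that list MYC, a growth regulator with distant enhancers, held 155 and 273 nodes. On chromosome 6, where the cliques that list CITED2 held 78 and 247 nodes, nodes numbered 34 and 105 (140000001 to 141000000) and 7 and 84 (141000001 to 142000000). The region of the BMP2 cliques on chromosome 20 (6000001 to 7000000) held 24 and 98 nodes, that of the TBX3 and TBX5 cliques on chromosome 12 (115000001 to 116000000) 74 and 145, and that of the cliques of DUSP4, an ERK phosphatase, on chromosome 8 (29000001 to 30000000) 70 and 140.

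Regions with fewer OIS nodes, named in the same way, included those of the cliques that list NFAT5, NQO1 and WWP2 on chromosome 16 (69000001 to 70000000; 132 and 67 nodes), LITAF and SOCS1 on chromosome 16 (11000001 to 12000000; 135 and 73), and CCDC85C and CYP46A1 on chromosome 14 (100000001 to 101000000; 108 and 45). The others were those of the proliferating cliques that list BBC3, a p53 target, on chromosome 19 (47000001 to 48000000; 123 and 63), SREBF1, a regulator of lipid synthesis, and RAI1 on chromosome 17 (17000001 to 18000000; 113 and 55), and NFKB2 on chromosome 10 (104000001 to 105000000; 118 and 61). Of 2552 regions with nodes, 1279 had more nodes in OIS after scaling and 1273 fewer. At least 2-fold more were found in 385 and at least 2-fold fewer in 123.

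All tests below were chosen after the patterns had been seen, the 1 Mb window test also after the result over the same stretch, and the chromosome total after its node counts. SASP cytokine genes stood in larger OIS cliques, and a mere move of clique boundaries could produce this without more nodes nearby. Against random lists the median lay at percentile 99.6 over the same stretch (0.15, −0.06 to 0.86), 99.99 in the 1 Mb window (0.34, 0.07 to 0.76), 97.9 with 1 gene per OIS clique (0.68, −0.23 to 1.71) and 99.4 with matching on gene density (1.02, 0.19 to 2.09). With 1 gene per OIS clique it lay at percentile 99.9 in the window (0.27, −0.07 to 0.41) and 98.8 with matching on gene density (0.68, −0.23 to 1.71). Stretch and window are placed by the cliques that list a gene, so these ranks depend on clique size and cannot decide on moved boundaries. Over all names, the median log2 ratio of the stretch was 0.27 for those listed in OIS only and −0.41 for those in proliferating cells only. The other ranks argue against shared cliques or gene density as the whole reason, but neither is excluded. With 1 gene per OIS clique, which leaves 17 of 23 genes, each interval reaches below 0 and into the central 95% of random lists. Depth, batch and sequence composition could not be tested.

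Cell cycle genes such as FOXM1, CDC20 and CDC6 were listed in smaller OIS cliques or none. Over the same stretch the list median was −0.23 (−0.50 to −0.10), at percentile 18.5, and in the 1 Mb window −0.21 (−0.40 to −0.05), at percentile 39.85. Both intervals lie below 0, so fewer OIS nodes lay around these genes as a set after scaling. Matched random lists also had medians below 0, of −0.15 over the stretch and −0.18 in the window. Both list medians stayed within the central 95% of random lists. Stretch and window are moreover placed by the listing cliques, so these values cannot decide on moved boundaries. Against random genes of like gene density the change in clique size lay at percentile 63.0. It lay at 43.0 with matching on clique size and at 52.8 against unmatched lists. The list thus stood apart under none of these, so the pattern was not particular to the cell cycle. With no departure to account for, the value at like gene density cannot decide on a role of gene-rich regions.

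Gene-rich chromosomes such as 19 and 22 had fewer OIS nodes and gene-poor ones such as 4 and 13 more, but gene-poor X and 18 had −2.00% and −2.56%, with scaled intervals that include 0. An equally smaller OIS total on every chromosome would leave no difference after scaling, whereas the intervals of 10 chromosomes lay off 0. Without scaling 7 chromosomes, 4 and 13 among them, had more OIS nodes, but no interval lay above 0. Within chromosomes, cliques with more gene names per Mb also had lower ratios (Spearman coefficient within chromosomes −0.287, −0.325 to −0.244 over redrawn chromosomes), which argues against an effect of whole chromosomes alone. A difference in depth, signal to noise or sequence composition between the libraries could have the same effect and was not testable here.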
